A study of uncultured soil microorganism with 20 samples.

How the data were processed

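Soil microbial functional genes were measured in 20 samples from the Qinghai-Tibetan region, 10 from alpine meadow and 10 from alpine-steppe meadow. Each sample mixed several cores of surface soil from a plot, per the labels' protocols. Genomic DNA was extracted with a soil DNA kit, labelled with the dye Cy3 by random priming, and hybridised to GeoChip, an oligonucleotide microarray whose probes target genes of known function in microorganisms. The values deposited by the authors are linear probe intensities in a table of the whole series, per the file headers and the values themselves. A blank cell was read as a probe that was not detected. The scanner, the background correction, the rule for calling a probe detected and the normalization are not given in the sources used here. Totals per sample differ, so the values had not been scaled to a common total over the listed probes.

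The table holds 80412 probes. Each probe has a gene name, used here as its gene family (866 names), and belongs to 1 of 16 functional categories. The category of carbon cycling is divided further into carbon degradation, carbon fixation and methane. Some genes are split over several names, such as amyA with separate names for Actinobacteria, Proteobacteria, Firmicutes and fungi, or nifH and nifH_2. A column for the source organism was not used here, so groups of source organisms were read from suffixes of the gene names and from categories. Probe sequences were not analysed here, and 0 per-sample columns lacked a sample.

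Samples were grouped by their titles. Alpine meadow replicate 10 has labels that disagree: its title and collection site give alpine meadow, its source name gives alpine-steppe meadow. It was kept in alpine meadow, and leaving it out was among the alternatives. Replicate numbers 1 to 10 occur in both meadow types, and nothing in the labels says that a number marks a shared plot or day. The 2 meadow types lie at different latitudes, so meadow type and site cannot be told apart. The labels give a latitude for each plot, and the plots of a meadow type lie within 1 minute of latitude of each other. No longitude is given. The p-values here measure only the spread between these samples.

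The following choices were made before the data were examined: the groups, the tests, the 22 gene families always named, the 25 gene lists and most of the alternatives. Detected probes, the Shannon index (natural log, over the relative signal of detected probes) and the log2 total signal per sample were compared with 2-sided permutation tests of the difference of means (100000 resamples), adjusted together by the method of Benjamini and Hochberg. Shares of total signal by category and by source group were tested the same way, each family of tests adjusted on its own. Composition was compared by PERMANOVA (adonis2, vegan 2.7.1 in R 4.3.3, 9999 permutations) on Bray-Curtis distances of relative signal, with betadisper for the dispersion. For each family, the signal of its detected probes was summed and divided by the sample's total signal. The log2 of this share was tested with limma 3.58.1 (lmFit and eBayes) where a family had signal in at least 5 samples of each group, and a family without signal in a sample was set missing there. Probes were tested in the same way on log2 of their share. Detection of each probe was compared with Fisher's exact test, 2-sided, for probes detected in 1 to 19 samples. Adjusted p-values follow Benjamini and Hochberg, with a threshold of 0.05. Differences are alpine-steppe meadow minus alpine meadow throughout, and intervals are 95% confidence intervals. The family intervals are not adjusted for the number of families. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

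The families named in the text follow a fixed rule. Up to 10 of the largest rises and 10 of the largest falls past the threshold were to be named. In addition, 22 families of carbon, nitrogen, phosphorus and sulphur cycling were always named where measured, together with up to 4 members per list with the smallest p. The 25 lists cover the degradation of starch, hemicellulose, cellulose, pectin, chitin, and lignin and aromatic compounds, carbon degradation by fungi, the glyoxylate cycle, carbon fixation, methanogenesis, methane oxidation, nitrogen fixation, nitrification, denitrification, dissimilatory and assimilatory nitrate reduction, ammonification, anammox, phosphorus cycling, sulphate reduction with sulphur oxidation, cold and heat shock, osmotic stress, oxygen limitation, oxidative stress, phosphate and nitrogen limitation, and antibiotic resistance. Name variants with suffixes beyond those foreseen were matched to the lists after the names in the table had been seen, and the mercury resistance gene set mer was kept out of methanogenesis. Lists were tested with limma's fry, whose PValue tests whether a list's families move, on balance, in a single direction, and whose PValue.Mixed tests for change in either direction. Neither compares a list with other families. Camera was run beside it, with the preset correlation of 0.01 and with an estimated correlation. Both tools used only families with signal in all 20 samples.

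Plant viruses with RNA genomes supply 206 probes in 36 gene sets. Their genomes are RNA and cannot be in a DNA extract, so their detection served as a background level. For families of 20 or more probes, the share of probes detected per sample was set against that of the virus probes with a sign-flip permutation test over the 20 samples (100000 resamples). This test does not take account of the spread between probe sets. A permutation test over probes was therefore added after the data had been seen, on the number of samples in which a probe was detected (100000 resamples, 2-sided). It treats the probes of a family as independent of each other. The 2 virus sets of 20 or more probes, coat_Nepovirus and RdRp_Nepovirus, were kept out of the 414 families and set against the other virus probes, to see what both tests give within the background.

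After the data had been seen, the arrays were divided by the spread (SD) of log2 signal over the 9676 probes detected on all of them, parted at 0.869 in the widest gap between arrays, into 7 arrays of narrow spread and 13 of wide spread. Comparisons were then run again with this class as a block and within each class. Permutation tests with a group of fewer than 10 samples, PERMANOVA included, took every split of the samples. The number of detected probes as a covariate, sums over probes detected in all samples, and merging of the name variants ending in _2 were also added at that point. The other alternatives concern scaling, filters on detection, the summary of a family, the test, the distance between samples, the replicate number as a block, and alpine meadow replicate 10.

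The procedure was tested on simulated data with changes of known size. In the same simulated data, 100 families were changed by 1.5-fold and 100 by 2-fold. Of these, limma recovered 77% and 93%, over 802 families, with 1.73% of calls false. With 100 probes changed by 1.5-fold and 100 by 2-fold together, it recovered 1% and 28%, over 46496 probes, with 6.45% of calls false. The adjustment is stricter where fewer features change, and recovery in that case was not simulated. All 5 lists changed by 1.5-fold were recovered. The simulated arrays had independent noise, unlike the correlated arrays measured here.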

Results

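Surface soil from alpine meadow (10 samples, at 40 degrees north) and from alpine-steppe meadow (10 samples, at 38 degrees north) was compared on GeoChip, a microarray of probes for microbial genes of known function. The study concerned the functional gene diversity of soil microorganisms under the degeneration of alpine meadow, with the loss of soil organic carbon as its stated subject. An array had between 18794 and 65397 detected probes, 23.4% to 81.3% of the 80412 probes listed. Detected intensities lay between 763 and 463126 in linear units. The lowest detected value differed between arrays. It was 763 in alpine meadow replicate 10, with 61926 detected probes, and 7398 in alpine-steppe meadow replicate 10, with 18794. Detected probes and the Shannon index were therefore not counted from a common lowest value. In all, 75624 probes were detected in at least 1 sample and 9676 in all 20 samples. The number of arrays limits the precision of each comparison.

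At each level of functional gene content examined, 0 differences between the 2 meadow types passed the threshold of the test. Genes of carbon cycling took the largest part of the signal of any category, 36.6% ± 1.63 (SD, n = 10) in alpine meadow and 36.3% ± 1.97 (n = 10) in alpine-steppe meadow. Nitrogen cycling genes took 9.69% ± 0.537 and 9.81% ± 0.370, and genes for resistance to metals 13.97% ± 1.28 and 14.6% ± 1.26. Of the listed probes, 29.7% belong to carbon cycling, 8.33% to nitrogen and 15.3% to metal resistance, so these shares also depend on the array's design. Samples of alpine meadow had 48814 ± 15846 detected probes and samples of alpine-steppe meadow 42361 ± 14835. The difference was -6453 probes (95% interval -20874 to 7967, adjusted p = 0.472, permutation test). The Shannon index of functional genes was 10.4 ± 0.303 in alpine meadow and 10.3 ± 0.332 in alpine-steppe meadow, a difference of -0.104 (-0.403 to 0.195, adjusted p = 0.472). The log2 total signal was 28.76 ± 0.27 and 28.62 ± 0.22, a difference of -0.14 (-0.37 to 0.10, adjusted p = 0.472).

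The arrays fell into 7 with a narrow spread of log2 signal over the shared probes (SD 0.715 to 0.783) and 13 with a wide spread (0.955 to 1.07). The narrow-spread arrays were 2 of alpine meadow and 5 of alpine-steppe meadow, the wide-spread arrays 8 and 5 (Fisher's exact test, p = 0.350). Within the wide-spread arrays, alpine-steppe meadow differed from alpine meadow by -6888 detected probes (exact permutation test, p = 0.368). Within the narrow-spread arrays the sign turned, with 7709 more in alpine-steppe meadow (exact p = 0.714). The Shannon index and the log2 total signal turned in the same way, with differences of 0.131 (exact p = 0.762) and 0.025 (exact p = 0.714) within the narrow-spread arrays. Within the wide-spread arrays they were -0.105 (exact p = 0.458) and -0.26 (exact p = 0.103). With the class as a block the difference was -2260 detected probes (exact permutation p = 0.739). In that setting it was -0.030 for the Shannon index (exact p = 0.836) and -0.17 for the log2 total signal (exact p = 0.144).

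**Figure D1:**
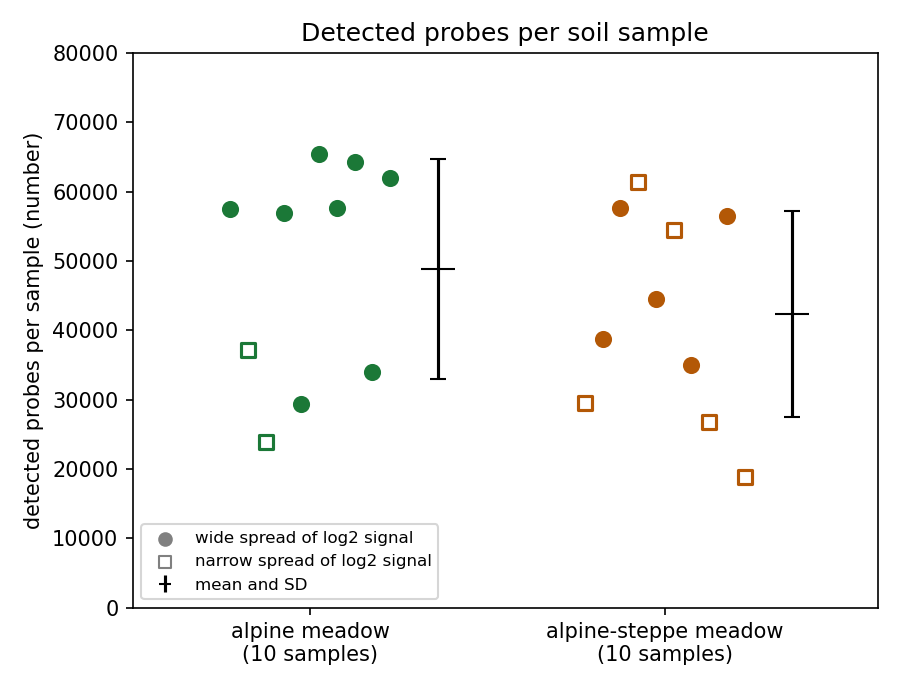
Number of detected probes per sample (vertical axis) in alpine meadow and alpine-steppe meadow, 10 samples each, with the mean and SD of each meadow type. The samples range from 18794 to 65397 detected probes, and the ranges of the 2 meadow types overlap.

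Community composition was compared over all probes. Meadow type accounted for 3.67% of the variation in Bray-Curtis distances (PERMANOVA, p = 0.592). The mean distance to the group centroid was 0.206 in alpine meadow and 0.226 in alpine-steppe meadow (p = 0.637). Meadow type accounted for 10.8% within the narrow-spread arrays (exact p = 0.714) and 4.25% within the wide-spread arrays (exact p = 0.754). The percentage that any grouping accounts for rises as arrays become fewer, so these percentages are not comparable with each other. Over the probes detected on all arrays, pairs of samples from the same meadow type had a mean correlation of 0.664 and pairs from different types 0.674. Alpine meadow replicate 10, whose labels disagree, had a mean correlation of 0.868 with the other wide-spread arrays of alpine meadow and of 0.871 with those of alpine-steppe meadow.

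Among genes of carbon degradation, the 95% intervals of the families always named lay within 1.5-fold in either direction. The amyA family, for alpha-amylase that opens starch, took 0.942% ± 0.0700 in alpine meadow and 0.957% ± 0.0746 in alpine-steppe meadow (n = 10 each), a log2 difference of 0.02 (SE 0.06). This family has 683 probes. Most alpha-amylase probes lie under other names, such as amyA_other (1828) and amyA_Actinobacteria (1454), and are not in this share. Endoglucanase, which cleaves cellulose chains internally, took 0.158% ± 0.0168 and 0.162% ± 0.0120 (0.04, SE 0.06), and cellobiase, which splits cellobiose into glucose, 0.212% ± 0.0253 and 0.204% ± 0.0244 (-0.05, SE 0.08). For xylanase, which acts on the xylan of hemicellulose, the shares were 0.118% ± 0.00771 and 0.114% ± 0.00455 (-0.05, SE 0.05). Endochitinase, which cleaves chitin, had 0.697% ± 0.0594 and 0.676% ± 0.0472 (-0.04, SE 0.06), and phenol_oxidase, which oxidises phenolic compounds, 0.481% ± 0.0320 and 0.471% ± 0.0258 (-0.03, SE 0.05). In limma, each of these had an adjusted p of 0.992.

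In the lists of carbon degradation genes, 0 members passed the threshold, and the member named first for a list is that with the smallest p. Starch degradation had 7 members with a higher and 12 with a lower mean share in alpine-steppe meadow (median log2 difference -0.06), with amyX, a pullulanase gene, at -0.29 (SE 0.23), apu, an amylopullulanase gene, at 0.27 (SE 0.21) and amyA_Proteobacteria at -0.27 (SE 0.22). For hemicellulose the members were 5 higher and 6 lower (median -0.01), with mannanase_fungi at -0.14 (SE 0.11), and for cellulose 4 and 6 (-0.01), with cellobiase_fungi at -0.19 (SE 0.16). Pectin had 7 and 8 (-0.00), with endopolygalacturonase_fungi at -0.29 (SE 0.17), and chitin 5 and 6 (-0.02), with chitinase_Oomycetes at 0.40 (SE 0.23). The list of lignin and aromatic compounds had 10 higher and 11 lower (median -0.01), with AssA, an alkylsuccinate synthase gene, at 0.35 (SE 0.17, p = 0.0566), glx_2, a glyoxal oxidase set, at -0.32 (SE 0.16, p = 0.0570) and LMO_2 at -0.32 (SE 0.18, p = 0.0879). The glyoxylate cycle had 2 higher and 4 lower (median -0.01), with AceB_fungi, fungal malate synthase, at -0.37 (SE 0.22). Fungal carbon degradation, where glx_2 also had the smallest p, had 4 higher and 12 lower (median -0.07), and its families together took 1.31% ± 0.0781 of the signal in alpine meadow and 1.27% ± 0.0857 in alpine-steppe meadow. Its fry p of 0.143 was the smallest of all 25 lists before adjustment.

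Of the carbon fixation and methane genes, 0 passed the threshold. Rubisco, the carboxylating enzyme of the Calvin cycle, took 0.396% ± 0.00897 in alpine meadow and 0.392% ± 0.0168 in alpine-steppe meadow (log2 difference -0.01, SE 0.04). The list of carbon fixation had 4 members higher and 8 lower (median -0.02), with CODH, carbon monoxide dehydrogenase, at 0.06 (SE 0.06). For mcrA, which encodes a subunit of the enzyme of the last step of methanogenesis, the shares were 0.145% ± 0.0374 and 0.129% ± 0.0301 (log2 difference -0.16, 95% interval -0.51 to 0.20). For pmoA, of the particulate methane monooxygenase, they were 0.105% ± 0.00901 and 0.0975% ± 0.0145 (-0.11, interval -0.30 to 0.07). Methanogenesis had 1 member higher and 2 lower (median -0.07), with hdrB_2, a heterodisulphide reductase set, at 0.30 (SE 0.13, p = 0.0360, adjusted p = 0.992). Methane oxidation had 3 higher and 1 lower (median 0.03). The log2 differences of mcrA and pmoA were -0.11 and -0.14 within the wide-spread arrays and 0.23 and 0.03 within the narrow-spread arrays, so both signs turned there.

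Among nitrogen cycling genes, narG, of the membrane-bound nitrate reductase, had the largest share, 1.47% ± 0.0807 in alpine meadow and 1.53% ± 0.122 in alpine-steppe meadow (log2 difference 0.06, SE 0.05). The nitrogenase gene nifH took 1.01% ± 0.152 and 0.972% ± 0.141 (-0.06, SE 0.10), and amoA, of ammonia monooxygenase, 1.16% ± 0.0993 and 1.20% ± 0.121 (0.04, SE 0.07). The nitrite reductase genes nirK and nirS had log2 differences of -0.02 (SE 0.06) and -0.01 (SE 0.05). The nitrous oxide reductase gene nosZ took 0.383% ± 0.0383 and 0.364% ± 0.0389 (-0.08, SE 0.07). The log2 difference was -0.05 (SE 0.05) for nrfA, of ammonia-forming nitrite reductase, 0.00 (SE 0.06) for ureC, a urease subunit gene, and -0.04 (SE 0.13) for gdh, glutamate dehydrogenase. In limma, ureC had an adjusted p of 0.998 and the others 0.992.

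Of the nitrogen lists, nitrogen fixation had 2 members higher and 1 lower (median 0.15), with nifH_uncult_bact at 0.21 (SE 0.18), and nitrification 4 and 2 (0.02). In nitrification, AmoA_Crenarchaeota stood at 0.22 (SE 0.27) and hao, hydroxylamine oxidoreductase, at -0.24 (SE 0.31). Denitrification had 7 higher and 4 lower (median 0.02), with 3.94% ± 0.239 of the signal in alpine meadow and 4.00% ± 0.206 in alpine-steppe meadow. Dissimilatory and assimilatory nitrate reduction had 5 and 6 (median -0.02), with NiR, a nitrite reductase set, at 0.16 (SE 0.08, p = 0.0647). Ammonification had 3 and 1 (0.02), and anammox 0 and 2 (-0.10), with hzo, hydrazine oxidoreductase, at -0.11 (SE 0.11).

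In phosphorus cycling, ppk, polyphosphate kinase, had a log2 difference of -0.03 (SE 0.07), ppx, exopolyphosphatase, 0.04 (SE 0.05), and phytase, which releases phosphate from phytate, -0.09 (SE 0.09). The list had 2 members higher and 6 lower (median -0.07), with phytase_fungi at -0.23 (SE 0.16). In the sulphur cycle, dsrA, of dissimilatory sulphite reductase, took 0.938% ± 0.0596 in alpine meadow and 0.910% ± 0.0756 in alpine-steppe meadow (log2 difference -0.05, SE 0.06). Its list, sulphate reduction with sulphur oxidation, had 15 higher and 9 lower (median 0.04), with APS_AprA_2, of adenylylsulphate reductase, at 0.16 (SE 0.09). All these families had an adjusted p of 0.992 in limma.

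After division by total signal, most members of the stress gene lists had a lower mean share in alpine-steppe meadow, and 0 of these lists or members passed the test. Oxygen limitation had 0 members higher and 8 lower (median log2 difference -0.07, fry p = 0.357), with narI, of nitrate reductase, at -0.07 (SE 0.07) and cydA, of cytochrome bd oxidase, at -0.13 (SE 0.13). Oxidative stress had 1 higher and 5 lower (median -0.05), with katA, catalase, at -0.22 (SE 0.14). Osmotic stress had 1 and 3 (median -0.12), with proX at -0.23 (SE 0.17), and cold and heat shock 2 and 6 (-0.03), with GroES at -0.35 (SE 0.30). Phosphate and nitrogen limitation had 2 and 8 (-0.05), with glnR at -0.13 (SE 0.12), and antibiotic resistance 5 and 5 (-0.01), with B_lactamase at -0.08 (SE 0.10).

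Of the 22 families always named, 6 kept the sign of their log2 difference within both classes of arrays: endoglucanase, endochitinase, phenol_oxidase, rubisco, nifH and ppx. For nifH the difference was -0.12 within the wide-spread arrays, -0.22 within the narrow-spread arrays and -0.15 with the class as a block. Over all arrays, the remaining sets of this gene were higher in alpine-steppe meadow, nifH_2 by 0.15 (SE 0.14) and nifH_uncult_bact by 0.21 (SE 0.18). With nifH_2 merged into nifH the difference was -0.01. The sign turned in at least 1 class for the other 16 named families. For amyA it was 0.04 within the wide-spread and -0.09 within the narrow-spread arrays, for ureC 0.05 and -0.07, and for gdh 0.01 and 0.21, with 0.08 for gdh with the class as a block. Without alpine meadow replicate 10, ureC turned to -0.01, while amyA (0.01), gdh (-0.01) and nirS (-0.00) kept their sign and changed by over 1.5 times. The other 18 changed less. In each of these settings 0 of the 22 passed the threshold.

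**Figure D2:**
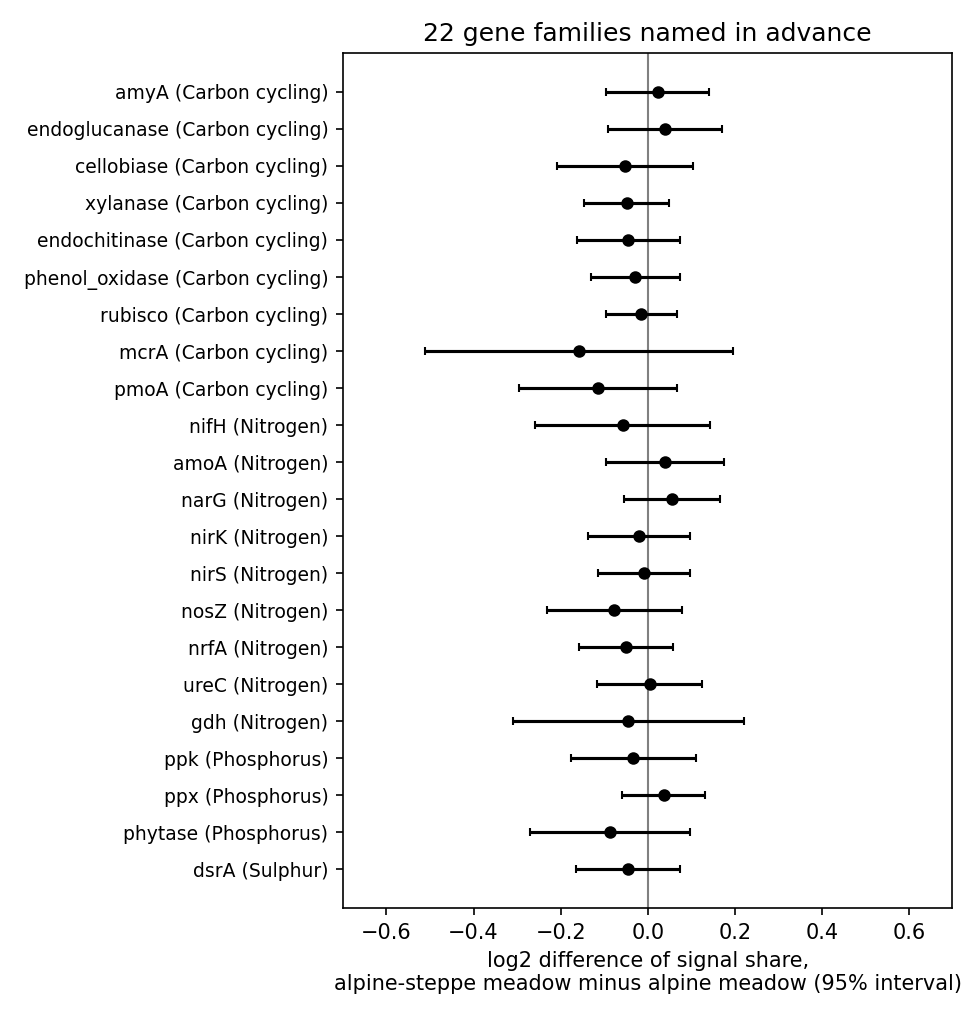
Log2 difference in share of total signal, alpine-steppe meadow minus alpine meadow, with its 95% interval from limma, for the 22 gene families always named (n = 10 per meadow type). All 22 intervals include 0 and lie within 1.5-fold in either direction. The sign depends on the scaling: without division by the total signal the 6 positive differences turn negative, and with the mean of detected probes in place of their sum the 16 negative differences turn positive.

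Over all 802 families tested, limma called 0, with a smallest adjusted p of 0.992. An unadjusted p under 0.05 was found for 12 families, where 40.1 are expected without any difference, and the rank-sum permutation test called 0, with 7 unadjusted. The mean share was higher in alpine-steppe meadow for 366 families and lower for 436, a balance set by the scaling, since the median log2 difference was -0.01 after division by total signal, -0.16 without it and 0.21 for the mean of detected probes in place of their sum. For 558 families the 95% interval lay within 1.5-fold in either direction, and for 746 within 2-fold. Larger differences in the remaining families are not excluded. Within the wide-spread arrays limma called 0 families (smallest adjusted p = 0.0799, 21 unadjusted) and within the narrow-spread arrays 0 (0.177, 10 unadjusted). Counts of probes, lists, categories and source groups called were also 0 within each of the 2 classes of arrays. The narrow-spread arrays, 2 against 5 samples, allow only 21 splits. Permutation tests over so few splits could hardly pass the adjustment, so the 0 for categories and source groups decides nothing in that class.

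Of the 25 lists, fry called 0 higher and 0 lower (smallest adjusted p = 0.967, 0 with an unadjusted p under 0.05). Camera also called 0 (smallest adjusted p = 0.489 with the preset correlation and 0.993 with an estimated correlation), and fry's test for change in either direction gave an adjusted p of 1. Members past the threshold numbered 0 when adjusted over all families and 0 when adjusted over the list alone. For 6 lists the median, the mean and the direction of fry differ in sign: chitin degradation, methanogenesis, methane oxidation, nitrification, nitrate reduction and antibiotic resistance.

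Of 46496 probes tested for their level, limma called 0 (smallest adjusted p = 0.996, 1104 with an unadjusted p under 0.05). With the replicate number as a block limma called 8 probes, all higher in alpine-steppe meadow (smallest adjusted p = 0.0377). Each rests on 3 to 6 complete pairs, and with the spread class as a block 0 probes were called. Both meadow types had at least 1 detection of 67721 probes, while 6110 were detected in alpine meadow alone and 1793 in alpine-steppe meadow alone. Mean detection of the plant RNA virus probes, the background level, was also lower in alpine-steppe meadow, 36.5% against 46.5%. Detection counts that favour alpine meadow are therefore not read as genes particular to it. Fisher's exact test called 0 of 65948 probes, with 309 at an unadjusted p under 0.05. Of these, 293 were detected more often in alpine meadow and 16 more often in alpine-steppe meadow. Without alpine meadow replicate 10 the count rose to 537, with 508 more often in alpine meadow and 29 more often in alpine-steppe meadow. Within the wide-spread arrays it was 231 (206 and 25). Within the narrow-spread arrays it was 23 and the balance turned, with 6 more often in alpine meadow and 17 more often in alpine-steppe meadow. Each of these settings also called 0 probes by Fisher's exact test. That test called 0 probes in all 99 other splits of the samples, including a split with 8298 at an unadjusted p under 0.05. Its 0 therefore does not show that detection was unchanged. Within the narrow-spread arrays, 2 against 5 samples allow only 21 splits, so a call was hardly possible there.

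Of the shares by functional category, 0 passed the threshold (smallest adjusted p = 0.844 over 16 categories and 3 parts of carbon cycling, with 0 at an unadjusted p under 0.05, permutation test). Genes of carbon degradation took 26.3% ± 1.44 of the signal in alpine meadow and 26.0% ± 1.83 in alpine-steppe meadow. Carbon fixation took 9.85% ± 0.326 and 9.94% ± 0.284, stress genes 8.20% ± 0.916 and 8.08% ± 0.795, and sulphur genes 5.55% ± 0.231 and 5.51% ± 0.256. Genes of organic remediation, for the breakdown of organic pollutants, took 11.3% ± 0.540 and 11.4% ± 0.429. The category of metal resistance had a difference of 0.668 percentage points (95% interval -0.524 to 1.86, p = 0.258), and that of fungal functions -0.240 points (-0.629 to 0.148, p = 0.217).

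By source organism, probes named for fungi took 3.86% ± 0.415 in alpine meadow and 3.61% ± 0.444 in alpine-steppe meadow (difference -0.258 points, interval -0.662 to 0.146, p = 0.209). Probes named for bacteria took 6.58% ± 0.805 and 6.49% ± 1.27, those for archaea 0.0763% ± 0.0185 and 0.0772% ± 0.0144, and those for bacteriophages 0.251% ± 0.0483 and 0.233% ± 0.0438. Of the 3764 probes named for bacteria, most belong to amyA sets (Actinobacteria 1454, Firmicutes 907, Proteobacteria 697). That share is therefore largely a share of alpha-amylase probes. The smallest adjusted p over the 6 source groups was 0.608 (permutation test), with 0 at an unadjusted p under 0.05.

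Probes for plant viruses with RNA genomes gave the background of detection. On average, 41.5% ± 20.1 of these probes were detected per sample (n = 20), against 56.7% ± 19.03 of all other probes. In alpine meadow the virus share was 46.5% and in alpine-steppe meadow 36.5%. In a permutation test over probes, 21 of the 22 named families were detected more often than the virus probes, adjusted over 414 families. Detection of narG was highest, 71.5% ± 14.5 of its probes, 30.1 points above the virus level (SD 7.22) and above it in 20 of 20 samples (adjusted p = 2.62e-05, from 1e-05, the smallest p that the resampling can give). The named families nearest to the virus level were pmoA, 6.81 points above (SD 4.16, 20 of 20 samples), which did not pass (adjusted p = 0.0793), and mcrA, 7.17 points above (SD 5.54, 17 of 20 samples, adjusted p = 0.0335). Probes of the virus set coat_Nepovirus were detected at 47.1%, 6.48 points above the other virus probes (SD 8.59, 17 of 20 samples, p = 0.321), and those of RdRp_Nepovirus at 37.4%, a difference of -4.54 points (SD 7.88, above in 6 of 20 samples, p = 0.525). A sign-flip permutation test over samples, chosen before the data were examined, parted these 2 background sets from the other virus probes (p = 0.00316 and 0.0185), so it was not used for calls. The probe sets differ in sequence, which was not taken into account.

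**Figure D3:**
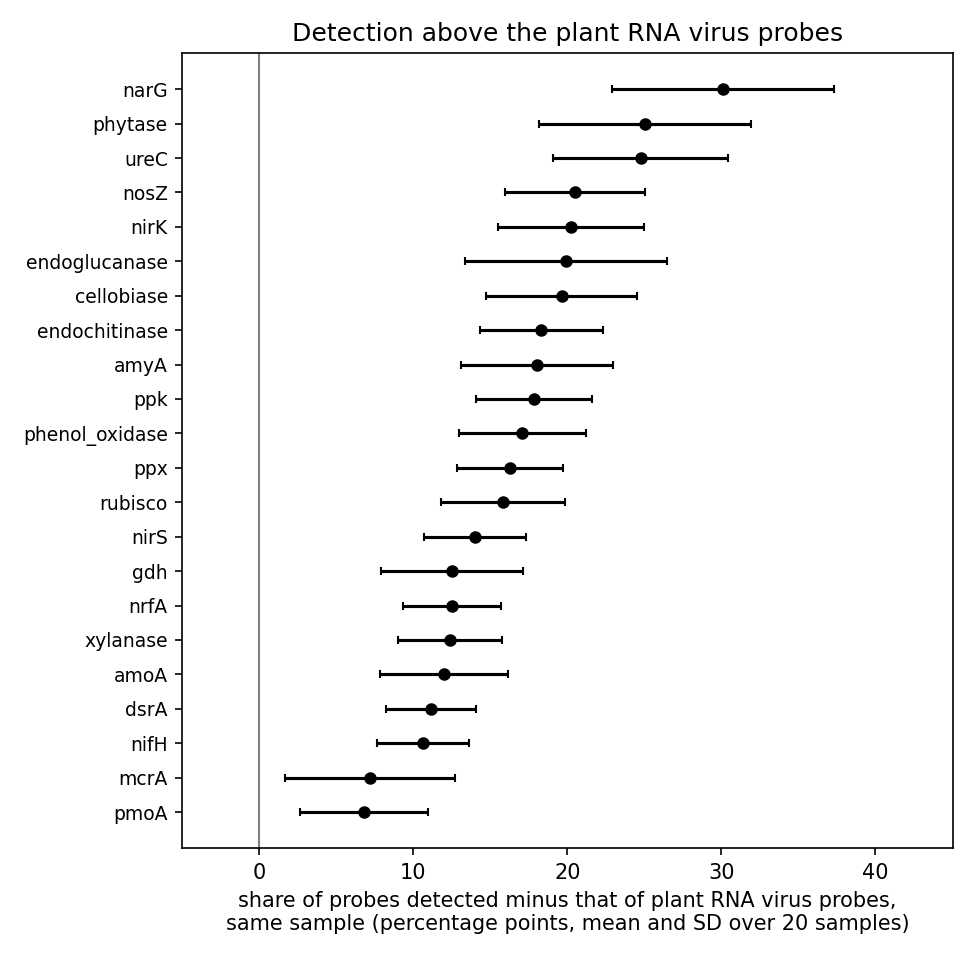
Share of a family's probes detected per sample, in percent, minus the share of plant RNA virus probes, for the named families, as mean and SD over 20 samples. The differences run from 6.81 points for pmoA to 30.1 points for narG.

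**Figure D4:**
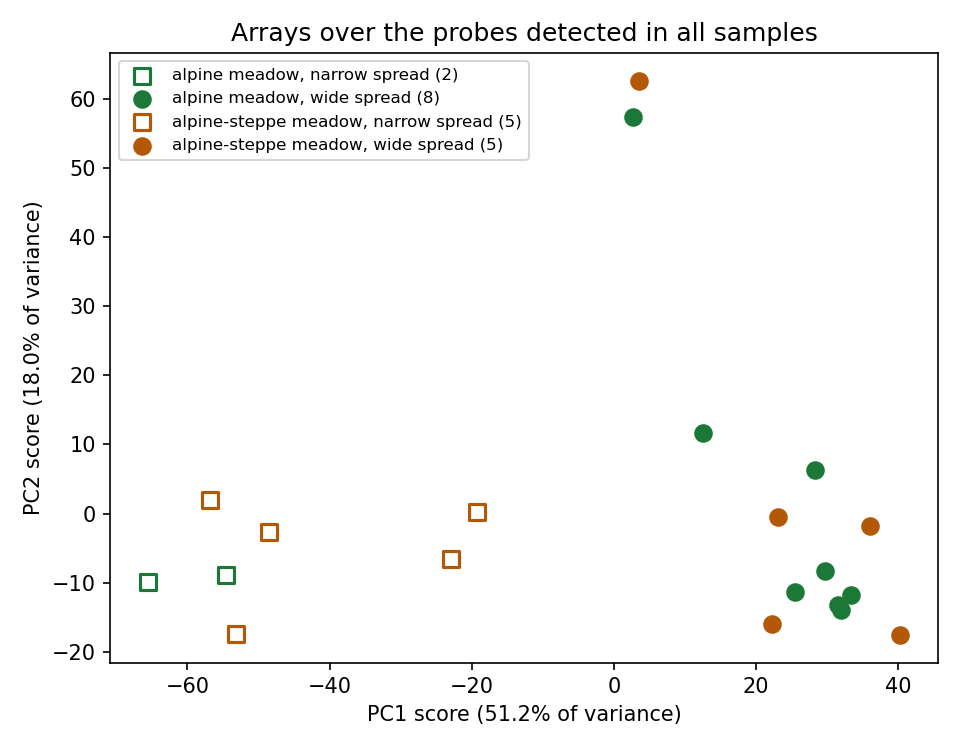
Position of the 20 arrays on the first principal components of log2 signal over the probes detected on all arrays, which hold 51.2% and 18.04% of the variance, marked by meadow type and by spread of signal. The 7 narrow-spread arrays lie apart from the 13 wide-spread arrays on the first component, and both sets hold arrays of both meadow types.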

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

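The tests of the share of plant RNA virus probes detected and of the correlations between arrays over these probes were chosen before their results were seen, and the tests of the number of detected probes, of taxon-dependent signal, of meadow type and of other splits of the samples were chosen after the result was seen.

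In 13 of 100 tests of a meadow type's 10 values, a sample stood further from its nearest neighbour than Dixon's limit allows, where chance alone gives 5. The tests use the same samples and are not independent, so a few unusual arrays can account for many flags. The 13 are therefore no evidence of a general excess. Alpine meadow replicate 5 accounted for 4 of the 13. Its share of signal from probes named for bacteria, mostly amyA probes, was 4.72%, with the next lowest at 6.25%. Cellobiase took 0.276% of its signal (next highest 0.233%), endochitinase 0.843% (0.743%) and phytase 0.0772% (0.0672%). Alpine-steppe meadow replicate 7 also accounted for 4. Phosphorus genes took 4.74% of its signal (next highest 3.68%), cellobiase 0.266% (0.218%), phenol_oxidase 0.536% (0.480%) and phytase 0.0856% (0.0680%). These 2 samples of different meadow types had cellobiase and phytase in common, and they stood at 57.5 and 62.7 on the second principal component, where the other arrays lay between -17.6 and 11.6.

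Alpine-steppe meadow replicate 10, the sample with the fewest detected probes, had 17.4% of its signal in metal resistance genes (next highest 15.2%), 1.82% in narG (1.602%) and 0.0646% in pmoA, with the next lowest at 0.0917%. Bioleaching genes took 0.731% of the signal in alpine meadow replicate 3 (next highest 0.621%) and 0.678% in alpine-steppe meadow replicate 8 (0.593%).

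Arrays of both meadow types parted by their spread of signal, with a mean correlation of 0.512 between narrow-spread and wide-spread arrays over the probes detected on all arrays and of 0.8286 among wide-spread arrays. Meadow type as the only cause is excluded by the 2 narrow-spread arrays from alpine meadow. Of the 7 narrow-spread arrays, 4 had a number of detected probes within the range of the wide-spread arrays and 3 had fewer. Their log2 ratio of amyA_Actinobacteria to amyA_Firmicutes signal lay within the range of the wide-spread arrays for 3 and below it for 4. Neither measure alone therefore sets the classes apart. A part played by the number of detected probes or by a taxon-dependent signal remains open. Correlations between arrays over the plant RNA virus probes alone followed those over all other probes (Mantel r = 0.912, p = 1e-04, the smallest the permutations can give). Virus probes may take up signal from soil DNA by cross-hybridisation, so their correlations could also follow a biological difference. The Mantel correlation therefore cannot tell an array-wide difference in hybridisation or scanning from a biological difference between samples. The first remains a hypothesis, and a biological difference within the sites remains untested.

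The wide-spread arrays also parted from each other along the first principal component, computed without amyA probes. The log2 ratio of amyA_Actinobacteria to amyA_Firmicutes signal followed it (rho = 0.698, permutation p = 0.0109, adjusted 0.0323, r = 0.862, p = 0.000210, adjusted 0.000560, n = 13), and so did the number of detected probes (rho = 0.665, permutation p = 0.0162, adjusted 0.0323, r = 0.853, p = 0.000280, adjusted 0.000560). Without the 2 arrays farthest from the median, r was 0.699 and 0.726, and rho was 0.509 and 0.455. Within the 7 narrow-spread arrays, the other part of these 4 relations, rho was 0.679 (exact p = 0.110, adjusted 0.146) and 0.50 (exact p = 0.267), while r was 0.952 (exact p = 0.00774, adjusted 0.0103) and 0.865 (exact p = 0.0308), values that rest on the 2 farthest arrays, without which r was 0.471 and -0.161. Both a difference in taxa and the number of detected probes could account for the parting of the wide-spread arrays, and both remain open.

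Detection was broad over the array. Plant RNA virus probes, whose targets cannot be in a DNA extract, were detected at 41.5% on average, which is 73.1% of the share of the other probes. Cross-hybridisation or background may give part of the detections. How large a part cannot be told apart here, because the sequence of the probes, which sets their cross-hybridisation, was not analysed.

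The absence of calls between the meadow types was set against other splits of the 20 samples into groups of 10. The real split gave 0 families, 0 probes, 0 probes by detection and 0 lists, which any split equals or exceeds, so that all 100 of 100 splits did so decides nothing. By unadjusted p, 74 gave at least as many families (12 in the real split), 59 as many probes (1104), 32 as many probes by detection (309) and 100 as many lists (0). The highest counts among the other splits were 123 families, 11148 probes, 0 probes by detection and 7 lists. The splits with most families, 123 and 108, were the only 2 of 99 that set all 7 narrow-spread arrays on the same side, so these counts point to a structure of the samples.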

How the results depend on the processing

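The tests with the spread class of the array, with the number of detected probes as a covariate, with sums over probes detected in all samples and with merged name variants were chosen after the result was seen.

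Of 89 values that answer a comparison under an alternative, 85 were as in the main analysis, 3 reversed and 1 moved. Most of the 89 are counts of calls or percentages of variation, which have no direction. Only the differences in detected probes, Shannon index and total signal could reverse. The 85 include counts of calls from tests that could hardly give any, as set out below for detection and for the narrow-spread arrays. Within the narrow-spread arrays alone, 2 against 5 samples, the difference in detected probes reversed to 7709, in the Shannon index to 0.131 and in log2 total signal to 0.025; the cause was not tested. With the replicate number as a block, limma called 8 probes higher and 0 lower in alpine-steppe meadow (smallest adjusted p = 0.0377). They belong to cda_2, ferredoxin_oxidoreductase, alkH, trkA, nifH_2, mer, dsrA and obgE, named after their values were seen. Each rests on 3 to 6 complete pairs, and 35 of the 36 pairs set a narrow-spread alpine-steppe array against a wide-spread alpine meadow array. With the spread class as a block their log2 differences ran from -0.53 to 0.14 (smallest adjusted p = 1.00); over all alternatives the smallest adjusted p of a probe ran from 0.0377 to 1.00. Deviations of same-numbered samples correlated between -0.643 and 0.481, above 0.1 in 3 of 10 pairs, and 0 of the alpine meadow samples correlated best with their own number. The block changed no other call, and it took the probes by detection at an unadjusted p under 0.05 from 309 to 38 (33 more often in alpine meadow, 5 in alpine-steppe meadow).

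The count of families called was 0 under every alternative run, with 3 to 27 at an unadjusted p under 0.05 against 12, and a smallest adjusted p between 0.0799 and 0.999. Counts of lists, of probes by detection, of categories and of source groups were also 0 under each alternative run. An unchanged 0 shows little for probes by detection, or for categories and source groups within the narrow-spread arrays, since a call was hardly possible in either case. Composition ran from 1.88% to 10.8% of the variation, with the highest value from the narrow-spread arrays alone, where fewer arrays raise the percentage. Without alpine meadow replicate 10 the difference in detected probes was -4997. Of 374 values of the 22 named families, 299 kept their sign, 75 changed it and 0 passed the threshold. The 299 include values whose sign was fixed. The replicate block, limma's trend and robust settings, and the filters on samples with signal and on probes per family left these log2 differences as they were. Scaling moved the median log2 difference of all families from -0.01 to -0.16 without division by the total, to -0.13 with centring on the shared probes and to 0.21 with the mean of detected probes, and the signs followed it. Fry and camera use only families with signal in all samples, so that filter gives nothing further for lists, and limma's trend and robust settings were not run for lists. Undetected values and an unstated background correction limit what low signals can show.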

Other observations

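The families singled out here, the permutation test over probes and the amyA ratios without a replicate or within a class of arrays were chosen after the result was seen, and the sign-flip test over samples was chosen before.

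Detection above the plant RNA virus probes extended over most families. Of 414 families of 20 or more probes, 308 were detected more often than the virus probes and 0 less often (adjusted p under 0.05, permutation test over probes). The sign-flip test over samples gave 378 and 14, but it also parted sets of virus probes from each other, so its counts are not relied on. The highest shares of detected probes were those of limEH_2, a limonene epoxide hydrolase set, with 82.9% ± 17.96 (SD, n = 20), of cutinase, which cleaves the cutin of plant surfaces, with 82.6% ± 9.47, and of CsoS2, a carboxysome shell gene, with 79.0% ± 12.3, each above the virus level in 20 of 20 samples (adjusted p = 2.62e-05 over probes). The sulphur oxidation genes soxC and soxV had 75.3% ± 12.9 and 74.8% ± 11.8. The family furthest below the virus level was ssb, the single-strand binding protein gene of bacteriophages, with 31.2% ± 22.4, a difference of -10.3 points that did not pass (adjusted p = 0.169 over probes).

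Detection of the amyA sets differed by source organism. Of the probes named for Actinobacteria, 78.2% ± 13.2 were detected (n = 20 samples), of those for Proteobacteria 64.4% ± 20.9, for other sources 55.4% ± 19.4, for fungi 51.3% ± 21.3 and for Firmicutes 49.1% ± 21.6. These sets were not tested against each other, and their probes differ in sequence. The log2 ratio of amyA_Actinobacteria to amyA_Firmicutes signal was 0.71 ± 0.44 in alpine meadow and 0.58 ± 0.38 in alpine-steppe meadow (p = 0.484, permutation test, n = 10 each), a difference of -0.13. The difference was -0.07 without alpine meadow replicate 10 (exact permutation p = 0.696), -0.13 within the wide-spread arrays (exact p = 0.529) and 0.30 within the narrow-spread arrays, where the sign turned (exact p = 0.381).

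The smallest unadjusted p between the meadow types belonged to T4_recomb_endonuclease, a phage recombination gene, with a log2 difference of -0.59 (SE 0.20, p = 0.00732). Its probes were detected at 39.3%, against 41.5% for the plant RNA virus probes (adjusted p = 0.791, permutation test over probes). Its detection was thus not told from background. Next by p were 2 sets of 2 probes each that were also lower in alpine-steppe meadow, nif at -0.50 (SE 0.16, p = 0.00741) and tcpA at -0.65 (SE 0.23, p = 0.0170). They had signal in 14 and 12 of the 20 samples, and samples without signal were left out of the test. The nickel resistance gene cnrC had the smallest p among families with a higher mean share in alpine-steppe meadow, with a log2 difference of 0.89 (SE 0.35, 1.85-fold with a 95% interval of 1.12 to 3.06, p = 0.0193). After it stood AVR1_Oomycetes, a pathogen gene set of 2 probes, with 1.65 (SE 0.64, p = 0.0195). All these had an adjusted p of 0.992 in limma, so none passed the correction over 802 families.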
